A study of Mus musculus with 10 samples.

How the data were processed

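Gene expression was measured on Affymetrix mouse arrays in mouse embryonic fibroblast (MEF) lines. The deposited table holds 10 arrays, 1 per sample, with 45101 probe sets each. Per the labels, cells were plated in 96-well plates, grown for 20 hours and either preshocked, which means heated in a water bath at 43 °C for 30 minutes and returned to the incubator for 3 hours, or left unheated and harvested at 23 hours. Lysates of 144 wells were pooled for each sample, RNA integrity was assayed by microfluidic electrophoresis, and 1.5 µg of total RNA was labelled with biotin in a one-cycle protocol. The labels name a line without Hsp70, (-/-) or knockout, and a line with it, (+/+) or rescue. They do not state whether the samples of a group were separate cultures, so the p-values measure the spread between these samples.

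The deposited values are intensity on a linear scale, 1 value per probe set and array, made by the authors with summarisation software that is not given in the sources used here. The mean intensity after trimming 2% of the probe sets at each end lay between 500.003 and 500.004 in every array, which is what scaling each array to a common target gives. The array medians of the log2 values differed by up to 1.08, more than the tolerance of 0.2 set for keeping the deposited scaling, so the log2 values were quantile normalized with limma. Values below 1 (4935 of them) were first set to 1. The 64 Affymetrix control probe sets were left out of the gene fits, 34945 probe sets had exactly 1 gene symbol, 932 had several and 9160 had none. For each of 18193 genes the probe set with the highest mean was used, and the 60% of genes with the highest mean signal, 10915 genes, were tested. Signal over background was not given per probe set, and the number of arrays limits the precision.

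Groups were KO-labelled preshocked (3 arrays), KO-labelled unheated (3), rescue-labelled preshocked (2) and rescue-labelled unheated (2). One limma model (version 3.58.1, R version 4.3.3, statmod version 1.5.0) with a mean for each group gave moderated statistics for 5 comparisons. They were preshocked against unheated in each line, the difference of these responses (rescue minus KO), and rescue against KO in unheated and in preshocked cells. P-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors from this model. The named genes are the 10 largest rises and the 10 largest falls among the called genes in which the arrays of the groups did not overlap. They are 5 each way, with no condition on overlap, for the preshocked lines and the difference of responses, and up to 4 members with the smallest adjusted p of each list described. Every array of one group lies above every array of the other by chance for 10% of genes with 3 against 3 arrays, 33.3% with 2 against 2 and 20% with 2 against 3. Probe sets of Hspa1a and Hspa1b were fitted with all other probe sets whatever their level.

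Gene lists were 35 in number with 569 genes, of which 526 were on the arrays with 1 symbol and 432 were among the genes tested. They were the Hsp70 and Hsp110 family, Hsp70 cochaperones, Hsp90 machinery, small heat shock proteins, mitochondrial chaperones and proteases, the chaperonin TRiC and prefoldin, other heat-inducible genes, ER chaperones and the unfolded protein response, ATF4 and the integrated stress response, proteasome subunits, NRF2 and oxidative stress, metallothioneins and metal response, immediate early genes, p53 targets, G2 and M phase, G1 to S and DNA replication, apoptosis regulators, NF-kB and inflammatory genes, interferon-stimulated genes, antigen presentation, extracellular matrix and fibroblast genes, actin cytoskeleton and SRF targets, cholesterol synthesis, ribosome biogenesis, glycolysis and hypoxia, histone genes, Hox genes, sex-linked genes, and markers of epithelial, macrophage and leukocyte, endothelial, muscle, adipocyte, cartilage and bone, and neural cells. The 31 lists with at least 3 measured members were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. fry tests whether the genes of a list move 1 way on balance and compares them with no other genes. cameraPR, which ranks genes by their moderated statistic, stood in for camera in the robust fit and in the blocked comparisons between lines.

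The labels number the arrays, and each preshocked array has an unheated array of its line with the next number (5 and 6, 11 and 12, 13 and 14, 31 and 32, 43 and 44). Pairing by these numbers was checked by correlating, over 10915 genes, the deviations of the arrays from their group means. The correlations were 0.721, 0.376, 0.552, 0.370 and 0.370, and the best partner of each array was the array with the adjoining number. With 2 arrays per group the rescue-labelled pairs mirror each other, so their correlations are equal by construction. The best partners of the rescue-labelled arrays are for the same reason a single result, not separate ones. A fit with the pairs as a block was run as an alternative for every comparison, as a fixed block within lines and for the difference of responses, and with duplicateCorrelation between lines. Its counts of called genes, and of called list members where they differ, stand beside those results.

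The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Those alternatives were the deposited values without quantile normalization, arrays centred on their medians, no filter on dim genes, the 40% of genes with the highest mean, an offset of 16 before the logarithm, an intensity trend or a robust estimate in the variance model, only the arrays of the compared groups, the mean of all probe sets of a gene, the pair block, array weights, a minimum change of 1.5-fold, and leaving out each array in turn. Where an array left out leaves 1 array in its group, that array is assumed to vary like the other groups. Leaving out the pair labelled 5 and 6, alone and with the block, was chosen after seeing the data, as was a list of imprinted genes. A correlation between the responses was taken as moved when it changed by more than 1 SD of its values with 1 array left out.

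The procedure was tested on simulated data of the same size, with changes of 1 or 2 on the log2 scale added to 100 genes each. The noise was drawn separately for each gene. Variation that genes share across arrays was therefore left out, and the false calls do not describe data that hold it. Without the block it called 51% and 85% of them within the KO-labelled arrays, 30% and 76% within the rescue-labelled arrays, and 15% and 58% for the difference of responses. Of the 10715 genes with no change, it called 1, 0 and 0. For the unheated lines it called 31% and 78%, with 13 false calls, and for the preshocked lines 48% and 76%, with 18 false calls. With the block, the preshock comparison called 61% and 88% with 5 false calls in the KO-labelled arrays, and 55% and 81% with 12 false calls in the rescue-labelled arrays. For measures with 1 value per array, such as the control probe sets, exact two-sided permutation tests were used. Gene positions are from the RefSeq annotation of GRCm38.p6.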

Results

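The arrays compared mouse embryonic fibroblasts from a line labelled hsp70 (-/-), called KO-labelled here, with fibroblasts from a line labelled (+/+) rescue, called rescue-labelled here. In each line, cells preshocked at 43 °C for 30 minutes and harvested 3 hours later were set against unheated cells, as a measure of the transcripts present when thermotolerance is assessed. The KO-labelled groups had 3 preshocked and 3 unheated arrays, and the rescue-labelled groups had 2 and 2. Median deposited intensities lay between 50.5 and 73.5 in 8 arrays. In KO-labelled preshocked replicate 1 and KO-labelled unheated replicate 3, numbered 5 and 6 in the labels, they were 100.2 and 106.8, and the first principal component, with 35.3% of the variance, set this pair apart. The second component, with 19.2%, separated preshocked from unheated arrays. The ratios of 3' to 5' signal of Gapdh were alike in the preshocked and unheated KO-labelled arrays, at -0.255 ± 0.042 and -0.258 ± 0.054 (log2, SD, n = 3 each, exact permutation p = 1 of a smallest possible 0.1). The 18S ribosomal RNA control was lower in the rescue-labelled arrays, by -2.22 log2 at its 3' probe set and by -2.18 at its middle probe set (n = 4 and 6, exact permutation p = 0.00476 for each, the smallest possible, 0.05 after adjustment over the 21 comparisons of control probe sets). That p treats paired arrays as independent, and over the means of 2 and 3 pairs it was 0.1 for each, the smallest possible. Its 5' probe set differed by -1.33 (exact permutation p = 0.138, n = 4 and 6), with 8.995 ± 1.830 in the rescue-labelled arrays (SD): the pair numbered 31 and 32 stood at 7.595 and 7.238, and the pair numbered 43 and 44 at 10.49 and 10.66, within the KO-labelled range of 9.54 to 11.11.

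Hspa1b, which encodes an inducible Hsp70 chaperone, rose in both lines after preshock, the line labelled knockout included. Hspa1b is gene 15511 on chromosome 17, from 34956429 to 34959238 of GRCm38.p6. On its probe set with the largest rise the deposited intensity went from 79.5 ± 23.5 in unheated to 23077 ± 6359 in preshocked KO-labelled arrays (SD, n = 3 each), and from 229.2 ± 46.6 to 33049 ± 5430 in rescue-labelled arrays (SD, n = 2 each). The log2 changes in KO-labelled arrays were 8.48 ± 0.32, 7.78 ± 0.33 and 6.81 ± 0.41 (SE) on its 3 probe sets, with adjusted p of 4.51e-04, 5.26e-04 and 0.00289 over all probe sets. In rescue-labelled arrays they were 6.95 ± 0.40, 6.55 ± 0.41 and 5.60 ± 0.51, with adjusted p of 0.00679, 0.00679 and 0.0364. Between the preshocked lines the same probe sets differed by 0.29, 0.39 and -0.13 log2 (adjusted p from 0.836 to 0.965), and between the unheated lines by 1.82, 1.62 and 1.07 (adjusted p from 0.241 to 0.629). The difference of responses was -1.53, -1.23 and -1.20 (adjusted p = 1 for each). In preshocked arrays these probe sets lay at percentiles 99.57 to 99.96 of their array. That is near the top of the normalized scale, so differences between the preshocked lines may be understated. The neighbouring gene Hspa1a had 1 probe set, near the floor in every group, at 12.3 ± 8.5 in preshocked KO-labelled arrays (SD, n = 3), and its log2 changes of 0.45 and -1.05 in the KO-labelled and rescue-labelled arrays were not called. A probe set outside the deleted part of a gene checks nothing about a knockout, and the position of these probe sets relative to the deletion is not known here. The rise leaves the knockout label in question without settling it, and this limit holds for each direction drawn between the lines. With the pair block the calls over all probe sets ended in KO-labelled arrays (adjusted p from 0.0931 to 0.108) and in rescue-labelled arrays (0.261 to 0.263), while in the fit of named genes Hspa1b stayed called in both (0.00543 and 0.0243). Over all probe sets, the 3 rescue-labelled calls also ended without rescue preshocked replicate 1 (adjusted p up to 0.284), rescue preshocked replicate 2 (up to 0.172), rescue unheated replicate 1 (up to 0.170) or rescue unheated replicate 2 (up to 0.153).

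**Figure D1:**
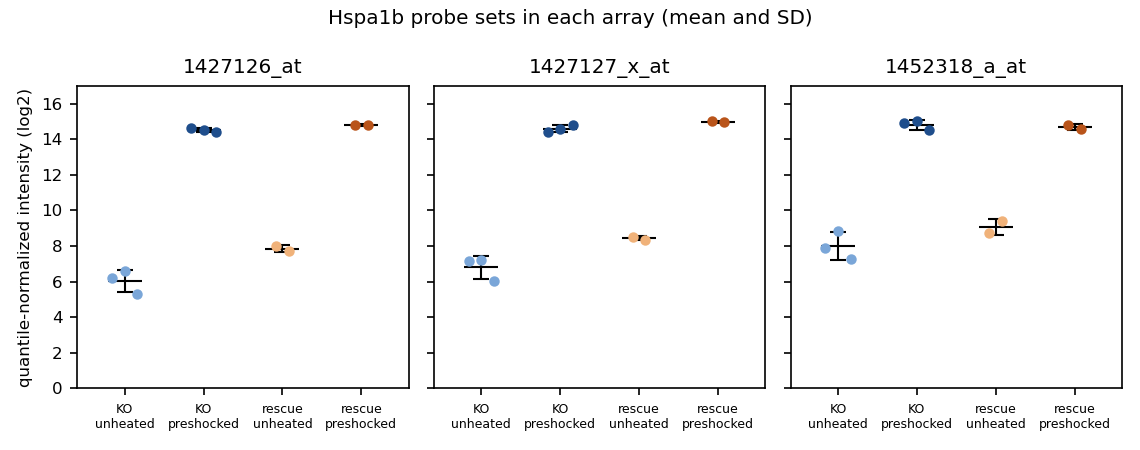
Quantile-normalized intensity (log2) of the 3 Hspa1b probe sets in each of the 10 arrays, by group, with points for arrays, a horizontal mark for the mean and bars for the SD. On the probe set with the largest rise the group means went from 6.03 to 14.51 in KO-labelled and from 7.85 to 14.79 in rescue-labelled arrays.

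In KO-labelled fibroblasts the largest rises at 3 hours after preshock among the called genes were in Hspa1b (6.81 ± 0.37 log2), Atf3, a stress-induced transcription factor (4.84 ± 0.33), Cpn1, a carboxypeptidase subunit (4.78 ± 0.20), Fpr2, a formyl peptide receptor (4.49 ± 0.83), and Dnaja4, a J-domain cochaperone (4.22 ± 0.55). Lor and Sprr1a, which encode proteins of the cornified envelope, rose by 2.98 ± 0.54 and 2.95 ± 0.37, Pgf, a placental growth factor, by 2.93 ± 0.27, Fosb by 2.92 ± 0.32 and Gadd45g by 2.86 ± 0.35. Lor had 1 of its 3 probe sets with the opposite sign. The largest falls were in Chst15, a sulfotransferase (-2.46 ± 0.45), and in the zinc finger genes Zfp799 (-2.17 ± 0.28), Zfp839 (-1.76 ± 0.28), Zfp324 (-1.53 ± 0.23) and Zfp322a (-1.51 ± 0.21). Ttc30b and Bbs10, which act in the primary cilium, fell by 1.79 and 1.55 on the log2 scale, and Abcc10, Jrk and Ppargc1b fell by 1.66, 1.64 and 1.53. In Cpn1, Fpr2, Chst15, Ttc30b, Bbs10 and Zfp324 the lower group had a mean of 3.76 to 5.55, below 5.65, the lowest mean of a gene tested, so the size of these changes is uncertain. These values are on arrays labelled knockout, in which the Hspa1b transcript rose.

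Among heat shock genes of the KO-labelled arrays, 2 of 9 measured members of the Hsp70 and Hsp110 family rose, Hspa1b and Hsph1 (1.90 ± 0.20), and 2 when adjusted over the list alone. The constitutive Hspa8 stood at 0.12 ± 0.14, but its unheated mean was already 14.93 log2, near the top of the normalized scale. Of 18 Hsp70 cochaperones, 4 rose (Dnajb1 by 2.64 ± 0.17, Dnajb4 by 2.06 ± 0.15, Bag3 by 1.68 ± 0.17, and Dnaja4), against 5 higher and 1 lower adjusted over the list alone. Of 5 small heat shock proteins, 3 rose (Hspb1 by 1.92 ± 0.26, Hspb8 by 1.28 ± 0.16, Cryab by 0.87 ± 0.16), and 4 adjusted over the list alone. Of 10 other heat-inducible genes, 3 rose (Dedd2 by 2.40 ± 0.24, Zfand2a by 2.34 ± 0.16, Csrnp1 by 1.94 ± 0.31), and 5 adjusted over the list alone. Hsp90 machinery had 0 of 13 members called by limma (1 at an unadjusted p under 0.05) and 0 adjusted over the list alone, with 11 values above 0, and 3 members called with the pair block (Hsp90aa1, Ahsa1 and Chordc1). The block called 3 members of the Hsp70 and Hsp110 family, 4 cochaperones as higher and 1 as lower, and 5 other heat-inducible genes. Of 4 genes of metal response, the zinc exporter Slc30a1 rose (1.29 ± 0.16), with 2 adjusted over the list alone, and Mt1 stood at -0.01 ± 0.22. camera called each of these 6 lists as higher, with adjusted p of 2.12e-04, 1.01e-05, 1.02e-06, 5.71e-08, 0.00845 and 0.00857 in the order given. None of the 6 calls held with an estimated correlation, where the values were adjusted p = 0.138, 0.141, 0.130, 0.138, 0.138 and 0.138 with an estimated correlation. By fry, which compares a list with no other genes, each of the 6 was higher (fry adjusted p from 0.00197 to 0.0157).

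Immediate early genes were the list with the most called members in the KO-labelled arrays: 9 of 25 rose and 1 fell, against 14 and 2 adjusted over the list alone, with a median of 0.73 log2. Fosb, Junb (2.10 ± 0.27), Egr1 (2.76 ± 0.38) and the phosphatase gene Dusp5 (1.71 ± 0.25) had the smallest adjusted p, and Klf2, named after its value was seen, fell (-1.27, adjusted p = 0.0176). camera gave adjusted p = 1.59e-11 for this list and adjusted p = 0.141 with an estimated correlation. Of 20 genes of ATF4 and the integrated stress response, Atf3 and Ppp1r15a (1.75 ± 0.22) rose, 2 higher and 1 lower passed adjusted over the list alone, and Atf4 itself stood at -0.53 ± 0.15 without being called, though it was lower with the pair block. That list had camera adjusted p = 0.00354 and adjusted p = 0.257 with an estimated correlation. Cholesterol synthesis was called as lower, with a median of -0.245 and 3 of 18 values above 0. Hmgcs1, which encodes HMG-CoA synthase, fell (-0.998 ± 0.173), 2 members passed adjusted over the list alone, and Sqle stood at -0.62 ± 0.14. With the block, 14 immediate early genes were higher and 3 lower, 5 genes of ATF4 and the integrated stress response were higher and 1 lower, and 4 genes of cholesterol synthesis were lower. The camera values of cholesterol synthesis were adjusted p = 0.0127 and adjusted p = 0.213 with an estimated correlation.

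The other lists were not called in the KO-labelled arrays, though some members were. Cdkn1a (1.48 ± 0.20) and Mdm2 (1.14 ± 0.20) rose among 13 p53 targets (list median -0.046), Vegfa (1.44 ± 0.20) rose among 17 genes of glycolysis and hypoxia (-0.044), and Cflar (0.99 ± 0.17) rose while Bid (-1.11 ± 0.21) fell among 15 apoptosis regulators (-8.03e-04). The counts adjusted over the list alone were 3 higher, 1 higher, and 2 higher with 3 lower. With the pair block, 2 genes of glycolysis and hypoxia were higher and 1 lower, and 2 apoptosis regulators were higher and 2 lower. In lists with 0 members called by limma without it, the block called 2 genes of G2 and M phase as higher, 1 higher and 2 lower among extracellular matrix and fibroblast genes, and 1 each way among ER chaperones and the unfolded protein response, NRF2 and oxidative stress, and NF-kB and inflammatory genes. It called 1 as lower among mitochondrial chaperones and proteases, G1 to S and DNA replication, ribosome biogenesis, histone genes, and macrophage and leukocyte markers. List medians were 0.020 for mitochondrial chaperones and proteases, 0.020 for the chaperonin TRiC and prefoldin, 0.066 for ER chaperones and the unfolded protein response, -0.0011 for proteasome subunits, 0.027 for NRF2 and oxidative stress, 0.061 for G2 and M phase and -0.0040 for G1 to S and DNA replication. They were -0.017 for NF-kB and inflammatory genes, -0.110 for interferon-stimulated genes and 0.079 for antigen presentation. Others were 0.0079 for extracellular matrix and fibroblast genes, -0.021 for actin cytoskeleton and SRF targets, -0.085 for ribosome biogenesis, -0.322 for histone genes and 0.104 for Hox genes. Histone genes were lower by fry (adjusted p = 9.00e-04, camera adjusted p = 0.131, 4 of 6 values below 0). Among markers of other cell types limma called 0 members (1 unadjusted, among macrophage and leukocyte markers), with medians of -0.907 (epithelial, 3 genes), 0.265 (macrophage and leukocyte, 4), 0.259 (muscle, 5) and 0.162 (neural, 5). Lists with fewer than 3 measured members were not tested: their log2 changes were 0.05 for Xist (sex-linked genes), 0.63 and 2.62 for Kdr and Esam (endothelial), 0.18 for Cebpa (adipocyte), and 2.00 and 0.54 for Sox9 and Sp7 (cartilage and bone), of which Sox9 was called. The median differed in sign from the mean or from camera's direction for p53 targets, glycolysis and hypoxia, mitochondrial chaperones, proteasome subunits, extracellular matrix genes and actin cytoskeleton.

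In total limma called 193 of 10915 genes in the KO-labelled arrays, 103 higher and 90 lower, of which 134 changed at least 2-fold. The count was also lower without KO preshocked replicate 1 (142), KO preshocked replicate 2 (49), KO preshocked replicate 3 (93), KO unheated replicate 1 (77), KO unheated replicate 2 (58) or KO unheated replicate 3 (124). The pair block called 1000 genes (366 higher and 634 lower, 190 of the 193 among them), so that the share of higher genes went from 53.4% to 36.6%. With the arrays centred on their medians the count was 27 (24 higher and 3 lower, 88.9% higher), and with no filter on dim genes 28 (24 and 4, 85.7%). Of the 20 named genes, Hspa1b, Atf3, Cpn1, Sprr1a, Pgf, Fosb, Gadd45g and Ttc30b stayed called without each array. The number still called was 18 without KO preshocked replicate 1, 8 without KO preshocked replicate 2, 11 without KO preshocked replicate 3, 11 without KO unheated replicate 1, 12 without KO unheated replicate 2 and 17 without KO unheated replicate 3. The block ended the calls of Fpr2 (adjusted p = 0.0643, range over all alternatives 9.16e-04 to 0.142) and Chst15 (0.0589, range 0.0298 to 0.159). Of 25 called list members named by the rule, Bag3, Dedd2, Dnajb1, Dnajb4, Hspb8, Hsph1, Junb, Ppp1r15a, Slc30a1, Zfand2a, Atf3, Fosb and Hspa1b stayed called without each array. Counting these, 13 were still called without KO preshocked replicate 2, 15 without KO unheated replicate 2, 16 without KO unheated replicate 1, 20 without KO unheated replicate 3, 21 without KO preshocked replicate 1 and 22 without KO preshocked replicate 3. Among lists, the call of Hsp90 machinery ended without KO unheated replicate 3 (adjusted p = 0.0572) and that of cholesterol synthesis ended without KO preshocked replicate 1 (0.1497). G2 and M phase was called without KO unheated replicate 1 (0.0335, against 0.384 with all arrays and an estimated correlation).

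In rescue-labelled fibroblasts the largest rises after preshock among the called genes were in Hspa1b (5.60 ± 0.46 log2), Atf3 (4.98 ± 0.41), Cpn1 (4.74 ± 0.25), Sprr1a (4.07 ± 0.45) and Zglp1 (3.40 ± 0.50). The cochaperone genes Dnajb1 and Dnajb4 rose by 2.87 ± 0.20 and 2.44 ± 0.19, Fosb by 2.73 ± 0.40, Zfand2a, an arsenite-inducible zinc finger gene, by 2.35 ± 0.20, and the transcription factor Sox9 by 2.32 ± 0.31. Dnajb4 had 1 of its 3 probe sets with the opposite sign. The falls that passed were in Zfp324 (-2.08 ± 0.29), Xkr8 (-1.41 ± 0.16), Trim65 (-1.32 ± 0.14), 9130023H24Rik (-1.32 ± 0.20), Kif24 (-1.31 ± 0.19), the peroxisomal gene Pex26 (-1.24 ± 0.19), Tada1 (-1.20 ± 0.16), Ankrd1 (-1.18 ± 0.15) and Ttc30b (-1.12 ± 0.15). In Cpn1, Sprr1a, Zglp1 and Zfp324 the lower group had a mean of 3.28 to 4.57, below the lowest mean tested, so the size of these changes is uncertain.

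By list, the rescue-labelled arrays had 2 of 9 members of the Hsp70 and Hsp110 family called as higher (Hspa1b, and Hsph1 at 2.09 ± 0.24), and 3 of 18 cochaperones (Dnajb1, Dnajb4, and Bag3 at 1.67 ± 0.21). Of 5 small heat shock proteins 0 were called by limma (3 at an unadjusted p under 0.05, Hspb1 at 1.69 ± 0.31), and 1 with the pair block (Hspb8). The counts were 1 of 10 other heat-inducible genes (Zfand2a), 0 of 13 genes of Hsp90 machinery by limma (1 unadjusted), and 1 of 4 genes of metal response (Slc30a1 at 1.45 ± 0.19). Adjusted over the list alone the counts were 2, 4, 3, 5, 0 and 1. camera called these 6 lists as higher, with adjusted p of 0.00181, 3.08e-06, 9.11e-06, 6.54e-07, 0.0124 and 9.25e-04 in the order given. With an estimated correlation none of them passed: adjusted p = 0.178, 0.149, 0.123, 0.134, 0.149 and 0.123 with an estimated correlation. By fry, which compares a list with no other genes, each of the 6 was higher (fry adjusted p from 0.00314 to 0.0205). Of 25 immediate early genes only Fosb was called (with the pair block its call ended and Ier3 was called instead), with 10 higher and 3 lower adjusted over the list alone, a median of 0.284, camera adjusted p = 0.00108 and adjusted p = 0.448 with an estimated correlation. The 21 genes of G2 and M phase had 0 called members by limma (2 unadjusted) and 0 adjusted over the list alone, a median of 0.156 and 18 values above 0. Aurka stood at 0.55 and Prc1 at 0.56, and the list had camera adjusted p = 0.00175 and adjusted p = 0.178 with an estimated correlation. The 14 Hox genes had 0 called members by limma (2 unadjusted) and 0 adjusted over the list alone, with a median of 0.203, camera adjusted p = 0.0146 and adjusted p = 0.281 with an estimated correlation.

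Lists not called in the rescue-labelled arrays had medians of -0.079 for ATF4 and the integrated stress response, in which Atf3 rose, -0.188 for cholesterol synthesis (camera adjusted p = 0.0673), 0.025 for p53 targets, in which Cdkn1a rose (1.66 ± 0.25), and -0.082 for histone genes. With the pair block 1 member was called as higher among ER chaperones and the unfolded protein response and among genes of glycolysis and hypoxia. It called 1 as lower among apoptosis regulators, NF-kB and inflammatory genes, and cholesterol synthesis, and it ended the call of Cdkn1a among p53 targets. The block called proteasome subunits as higher (median 0.034, adjusted p = 0.0421, 0.206 without the block) and ribosome biogenesis as lower (median -0.100, adjusted p = 0.0323, 0.0702 without the block). With an estimated correlation, without the block, they had adjusted p = 0.741 and 0.338. Medians were -0.063 for mitochondrial chaperones and proteases, 0.013 for the chaperonin TRiC and prefoldin, 0.075 for ER chaperones and the unfolded protein response, 0.068 for NRF2 and oxidative stress and 0.028 for G1 to S and DNA replication. Further medians were -0.106 for apoptosis regulators, -0.069 for NF-kB and inflammatory genes, 0.026 for interferon-stimulated genes, 0.168 for antigen presentation, 0.034 for extracellular matrix and fibroblast genes, -0.040 for actin cytoskeleton and SRF targets and 0.030 for glycolysis and hypoxia. Markers of epithelial, macrophage and leukocyte, muscle and neural cells had medians of 0.545, 0.179, 0.074 and -0.031. The median differed in sign from the mean or from camera's direction for ATF4 and the integrated stress response (mean 0.265), apoptosis regulators, interferon-stimulated genes, actin cytoskeleton and neural markers. The call of Hsp90 machinery ended without rescue preshocked replicate 2 (adjusted p = 0.122) or rescue unheated replicate 2 (0.117), and that of Hox genes ended without rescue preshocked replicate 2 (0.321) or rescue unheated replicate 2 (0.198, with a median of -0.060). Cholesterol synthesis was called without rescue unheated replicate 2 (adjusted p = 0.0336), and extracellular matrix and fibroblast genes were called as higher without rescue preshocked replicate 1 (0.0388) or rescue unheated replicate 1 (0.0475). With all arrays these lists had adjusted p = 0.338 and 0.783 with an estimated correlation.

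limma called 39 of 10915 genes in the rescue-labelled arrays, 30 higher and 9 lower, each with a change of at least 2-fold. The count was 10 without rescue preshocked replicate 1, 10 without rescue preshocked replicate 2, 10 without rescue unheated replicate 1 and 12 without rescue unheated replicate 2, and 166 with the pair block (80 higher and 86 lower, 32 of the 39 among them). It was 7 with the arrays centred on their medians, all higher, and 10 with no filter on dim genes (9 higher and 1 lower). Of the 19 named genes, Hspa1b, Atf3, Cpn1, Dnajb1, Dnajb4 and Zfand2a stayed called without each array. The number still called was 7 without rescue preshocked replicate 1, 6 without rescue preshocked replicate 2, 6 without rescue unheated replicate 1 and 8 without rescue unheated replicate 2. Hsph1, Bag3, Slc30a1 and Cdkn1a lost their calls without each of the 4 arrays, and the block ended that of Cdkn1a (adjusted p = 0.0526). The block ended the calls of Zglp1 (adjusted p = 0.0582, range over all alternatives 0.00923 to 0.249), Fosb (0.0628, range 0.00623 to 0.237) and Kif24 (0.0530, range 0.0102 to 0.456).

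The responses of the lines resembled each other gene by gene. Of the 30 genes called higher in the rescue-labelled arrays, 29 were also called higher in the KO-labelled arrays, where 0.283 would be shared if the calls were independent, and of the 9 called lower 7 were shared (0.074 if independent). Atf3, Cpn1, Hspa1b, Sprr1a, Fosb, Dnajb1 and Zfand2a were among the shared rises, and Ttc30b, Xkr8 and Zfp324 among the shared falls. Across 10915 genes the log2 changes had a Pearson correlation of 0.650 and a Spearman correlation of 0.612, and 73.0% had the same sign. Genes are not independent replicates. The comparisons share no arrays, but both use the same estimate of each gene's spread, so their calls are not independent. The sign was the same for 192 of the 193 genes called in KO-labelled arrays, with Errfi1, named after its values were seen, as the exception (0.71 ± 0.14 and -0.0023 ± 0.17), and for all 39 called in rescue-labelled arrays. Errfi1 lost its call without KO preshocked replicate 1 (adjusted p = 0.0992), 2 (0.139) or 3 (0.0976) and without KO unheated replicate 1 (0.113), 2 (0.126) or 3 (0.118). The correlation was 0.175 with no filter on dim genes.

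**Figure D2:**
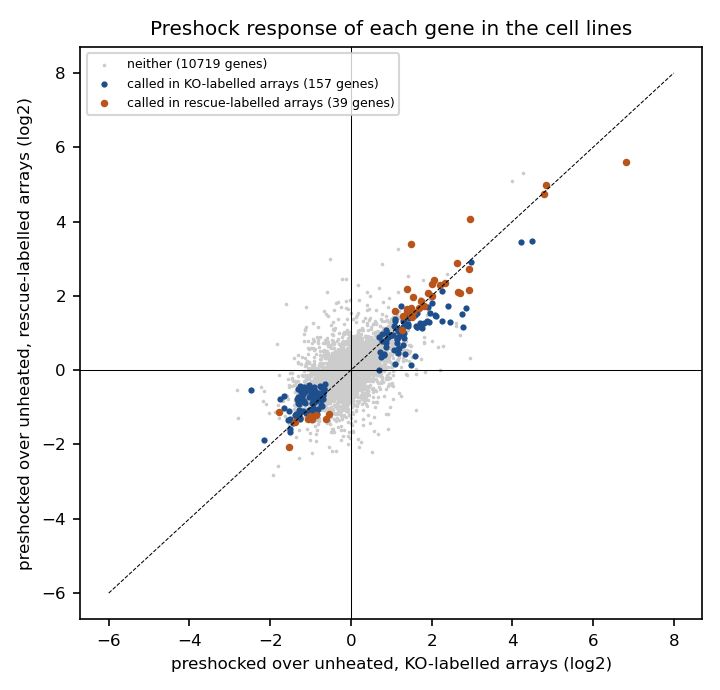
Log2 change after preshock in KO-labelled (x axis) and rescue-labelled arrays (y axis) for 10915 genes, with points for genes, colour for calls and a dashed line for equal changes. The called genes lie along the line, with Hspa1b at 6.81 and 5.60.

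No single gene was called for a difference of responses between the lines. limma called 0 of 10915 genes, with 103 at an unadjusted p under 0.05 and a smallest adjusted p of 1. The pair block also called 0, with 545 unadjusted. If no gene differed, a share of 0.05 of the genes would lie under that p by chance. The count of 103 without the block was well below that share, so that fit may miss differences. Immediate early genes had a smaller difference between preshocked and unheated cells in the rescue-labelled arrays by camera, with a median difference of -0.380 log2 (rescue minus KO), 2 of 25 values above 0 and adjusted p = 4.97e-08, but adjusted p = 0.769 with an estimated correlation and fry adjusted p = 0.919. The median was -0.197 without KO preshocked replicate 1 and -0.192 without rescue preshocked replicate 1, called in both cases (highest adjusted p with 1 array left out 0.0395). Between the lines the list had a median of 0.309 in unheated and -0.074 in preshocked cells (rescue minus KO). Among them Egr2 differed by -2.19, Fos by -1.62, Egr1 by -1.24 and Ier2 by -0.88 (adjusted p = 1 for each). ATF4 and the integrated stress response had a median difference of -0.146, 6 of 20 values above 0, adjusted p = 0.0105, and adjusted p = 0.769 with an estimated correlation. Histone genes had a median difference of 0.152 (rescue minus KO) and fry adjusted p = 0.0400, against camera adjusted p = 0.265. The heat shock lists were not called, with median differences of -0.123 for the Hsp70 and Hsp110 family, 0.045 for cochaperones, 0.021 for Hsp90 machinery, -0.120 for small heat shock proteins and 0.0054 for other heat-inducible genes (mean -0.119, camera's direction lower). The median also differed in sign from the mean or from camera's direction for antigen presentation, glycolysis and hypoxia, and muscle markers. The call of ATF4 and the integrated stress response ended without KO preshocked replicate 1 (adjusted p = 0.266), rescue preshocked replicate 1 (0.284), rescue unheated replicate 1 (0.457), KO unheated replicate 1 (0.0545), KO unheated replicate 2 (0.117) or KO unheated replicate 3 (0.0859). Without KO unheated replicate 1, Hox genes (adjusted p = 0.0356) and macrophage and leukocyte markers (0.0278, 4 genes) were called as responding more in the rescue-labelled arrays. With all arrays each had adjusted p = 0.779 with an estimated correlation.

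**Figure D3:**
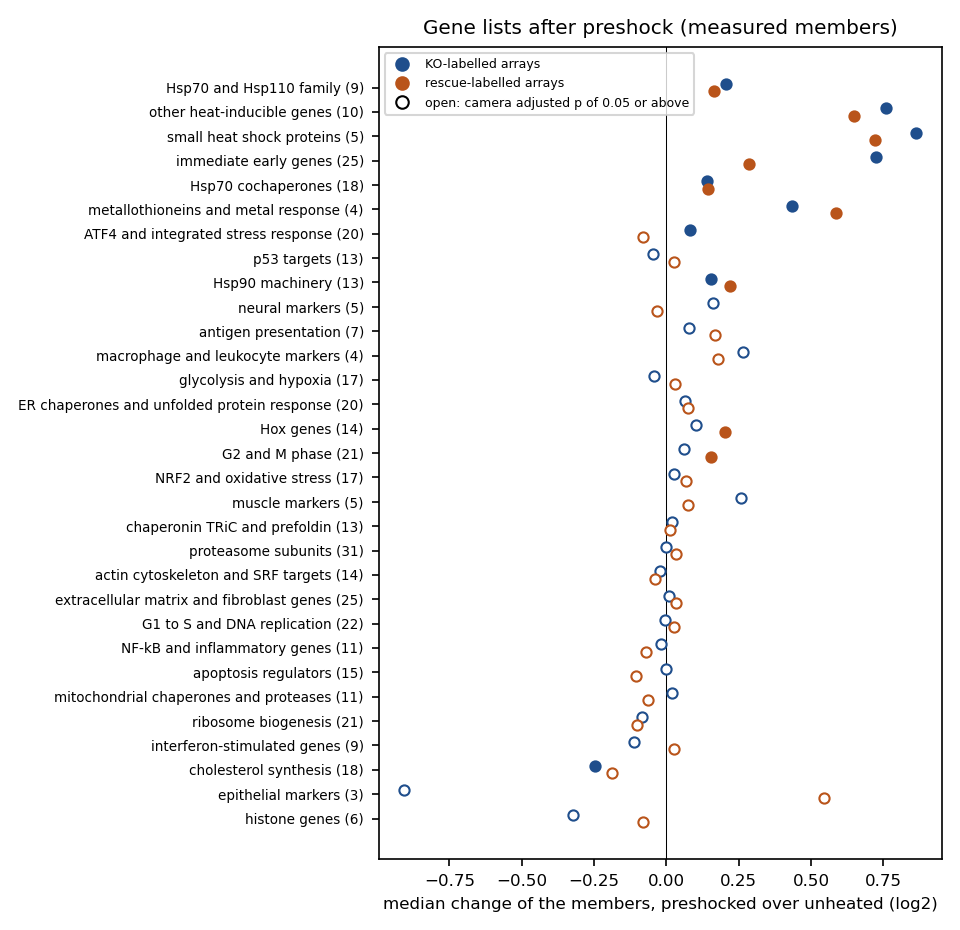
Median log2 change after preshock of the measured members of each list, in KO-labelled and rescue-labelled arrays, with filled points for lists called by camera at the preset correlation and open points for the others. Small heat shock proteins stood at 0.865 and 0.721, and cholesterol synthesis at -0.245 and -0.188. None of the filled points stayed called with an estimated correlation.

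Between unheated cells of the lines, Cdh11, a mesenchymal cadherin, was lower in the rescue-labelled arrays (-5.45 ± 0.74 log2), as were the imprinted genes Ndn (-5.26 ± 0.56) and Phlda2 (-3.52 ± 0.26), and Fez1 (-4.71 ± 0.37). Also lower were the p38 kinase gene Mapk12 (-4.45 ± 0.37), Klhl4 (-3.88 ± 0.49), C330022C24Rik (-3.11 ± 0.48), Fuom (-2.96 ± 0.35), the galectin gene Lgals3 (-2.83 ± 0.26) and the Wnt agonist gene Rspo2 (-2.77 ± 0.44). Higher in the rescue-labelled arrays were the glycosyltransferase gene B3galnt1 (5.64 ± 0.84), the ferroxidase gene Heph (3.01 ± 0.25), Sema5a (2.48 ± 0.28), Tepsin (2.38 ± 0.37) and the imprinted gene Peg3 (2.37 ± 0.38). So were Pgf (2.23 ± 0.30), Cotl1 (1.76 ± 0.26), the sulfotransferase gene Chst11 (1.75 ± 0.21), Pcgf2 (1.55 ± 0.22) and Tmem171 (1.47 ± 0.18). In Cdh11, Ndn, Fez1, Mapk12, Klhl4, C330022C24Rik and Fuom the rescue-labelled mean, and in B3galnt1 and Tepsin the KO-labelled mean, was 2.95 to 5.16, below the lowest mean tested (5.65). That signal is not shown to be above background, so the size of these differences and their order are uncertain. Sema5a, Klhl4 and Rspo2 each had 1 probe set with the opposite sign. These directions are between arrays labelled knockout and rescue, and Hspa1b itself was not called (1.07 ± 0.42, adjusted p = 0.334). The pair labelled 5 and 6, with the higher medians, and the higher 18S signal were in the KO-labelled arrays, and the line goes with the range of label numbers.

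Among the lists, immediate early genes were called as higher in the unheated rescue-labelled arrays, with a median of 0.309, and 22 of 25 values above 0. It had 0 called members by limma (7 at an unadjusted p under 0.05), and 0 adjusted over the list alone, with camera adjusted p = 0.00481 and adjusted p = 0.988 with an estimated correlation. That call ended without rescue unheated replicate 1 (adjusted p = 0.182) or KO unheated replicate 1 (0.0546). Of 25 extracellular matrix and fibroblast genes the protease inhibitor gene Timp3 was lower (-1.51 ± 0.22), with 5 higher and 3 lower adjusted over the list alone, and of 5 muscle markers Acta1 was lower (-1.41 ± 0.20), 1 adjusted over the list alone. Acta1 lost its call without each of the 5 arrays and Timp3 lost it without each but rescue unheated replicate 1. Cholesterol synthesis had a median of 0.158 (camera adjusted p = 0.360) and interferon-stimulated genes a median of -0.397 (camera adjusted p = 0.909). Of these, limma called 0 members (2 and 1 at an unadjusted p under 0.05), as among markers of epithelial (0 unadjusted), macrophage and leukocyte (0), and neural cells (1). Centring the arrays on their medians moved the median of all genes from -0.023 to 0.4995, and the median of immediate early genes to 0.866. The median of Hsp90 machinery, small heat shock proteins, other heat-inducible genes, p53 targets, G2 and M phase, antigen presentation, actin cytoskeleton and ribosome biogenesis differed in sign from the mean or from camera's direction.

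limma called 46 genes between the unheated lines, 12 higher and 34 lower in the rescue-labelled arrays, and 22 with the pair block (4 and 18). Without rescue unheated replicate 1 the count was 11, without rescue unheated replicate 2 it was 5 (Fez1, Heph, Ifitm10, Mapk12 and Phlda2, of which Ifitm10 was named after its values were seen). Without each KO-labelled array it was smaller too: without KO unheated replicate 1 it was 15, without KO unheated replicate 2 it was 7, and without KO unheated replicate 3 it was 22. Without the pair labelled 5 and 6 it was 95. Centred on the array medians, 19 of 32 called genes were higher, 59.4% against 26.1%. Of the 20 named genes, Heph, Fez1, Mapk12 and Phlda2 stayed called without each array. The number still called was 6 without rescue unheated replicate 1, 4 without rescue unheated replicate 2, 9 without KO unheated replicate 1, 5 without KO unheated replicate 2 and 14 without KO unheated replicate 3. The block ended the calls of B3galnt1 (adjusted p = 0.142), Tepsin (0.113), Peg3 (0.0841), Pgf (0.117), Chst11 (0.0665), Pcgf2 (0.0570), Tmem171 (0.117), Klhl4 (0.0514), C330022C24Rik (0.204), Fuom (0.142) and Rspo2 (0.135). Over all alternatives the adjusted p of these genes ran from 5.63e-04 (B3galnt1) to 0.4003 (Rspo2).

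After preshock the lines still differed in many of the same genes. Mapk12 (-4.79 ± 0.37), Fez1 (-4.54 ± 0.37), Ndn (-4.43 ± 0.56), Phlda2 (-3.36 ± 0.26) and Lgals3 (-2.45 ± 0.26) were lower in the rescue-labelled arrays, and Heph (2.79 ± 0.25), Sema5a (2.76 ± 0.28), Peg3 (2.70 ± 0.38), the protocadherin gene Pcdhb17 (2.47 ± 0.33) and the iron exporter gene Slc40a1 (1.97 ± 0.25) were higher. In Mapk12, Fez1, Sema5a, Pcdhb17 and Slc40a1 the lower group had a mean of 3.06 to 5.40, below the lowest mean tested, so these sizes are uncertain too. Peg3 had 2 of its 5 probe sets with the opposite sign. Of 37 called genes, 11 higher and 26 lower, 21 were also called between the unheated lines, each with the same sign. If the calls were independent, 0.156 would be shared. They are not independent: the comparisons share no arrays, but paired arrays deviate together and both use the same estimate of each gene's spread. The shared calls are therefore no replication of the differences between the lines. Timp3 (-1.44 ± 0.22) and Acta1 (-1.60 ± 0.20) were again lower, and both lost their calls without each of the 5 preshocked arrays. The pair block ended them in both states (adjusted p from 0.0536 to 0.117). No list was called by camera at the preset correlation, and cholesterol synthesis had a median of 0.263 (adjusted p = 0.206). Immediate early genes had a median of -0.074, and centring the arrays moved the median of all genes from -0.014 to 0.421. The Hsp70 and Hsp110 family, cochaperones, NRF2 and oxidative stress, NF-kB and inflammatory genes, extracellular matrix genes, actin cytoskeleton, Hox genes, and macrophage and leukocyte markers had medians that differed in sign from the mean or from camera's direction.

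The count for the preshocked lines was 15 without KO preshocked replicate 1, 8 without KO preshocked replicate 2, 4 without KO preshocked replicate 3 (Fez1, Heph, Mapk12 and Phlda2), 0 without rescue preshocked replicate 1 (limma, 1220 at an unadjusted p under 0.05), and 15 without rescue preshocked replicate 2. Centred on the array medians it was 22 (15 higher and 7 lower, 68.2% higher). It was 16 with the pair block (6 higher and 10 lower, 15 of the 37 among them), which ended the calls of Peg3 (adjusted p = 0.0578, range over all alternatives 0.00193 to 0.244) and Pcdhb17 (0.0721, range 0.00188 to 0.192). Of the 10 named genes, 8 stayed called without KO preshocked replicate 1, 6 without KO preshocked replicate 2, 4 without KO preshocked replicate 3, 0 without rescue preshocked replicate 1 and 5 without rescue preshocked replicate 2.

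**Figure D4:**
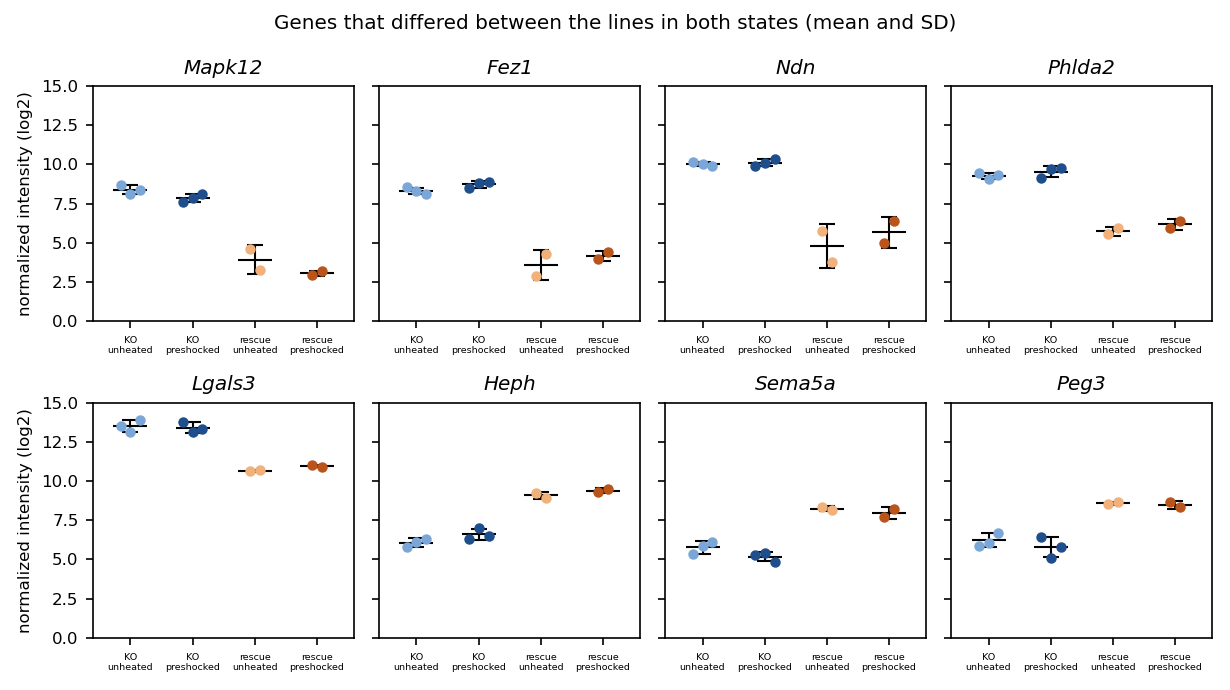
Normalized intensity (log2) of 8 genes that differed between the lines in both states, in each of the 10 arrays by group, with points for arrays, a horizontal mark for the mean and bars for the SD. Mapk12 stood at 8.39 and 7.85 in unheated and preshocked KO-labelled arrays and at 3.94 and 3.06 in rescue-labelled arrays. With the pair block Peg3 was no longer called in either state.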

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

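The tests of some or all arrays exchanged between lines, of related genes, of probe position, of smaller responses and of shared variation among immediate early genes were chosen only after the result was seen.

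The Hspa1b signal rose in arrays labelled knockout, by 6.81 to 8.48 log2 on its 3 probe sets. An exchange of some arrays between the lines is argued against, since 10 of 10 arrays lay nearer to the mean of their own line over genes chosen without the array, a test that an exchange of all labels would also pass, and an exchange of all labels is argued against as the source of the rise in a knockout by the smallest rise in rescue-labelled arrays, 5.60 ± 0.51 log2. Signal from related genes is argued against for those measured apart, since the largest rise among them was 1.90 log2 (Hsph1), while signal of Hspa1a on these probe sets was not tested, and the probe set of Hspa1a itself was near the floor and not called (0.45). Probe sets that lie outside the deleted part, or a line that still makes the transcript, cannot be told apart: the largest difference between the preshocked lines was 0.39 log2, and the position of the deletion is not given. A biological difference between the lines in the locus stays open and untested.

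Fewer genes were called in the rescue-labelled arrays (39) than in the KO-labelled arrays (193). With 2 against 2 KO-labelled arrays the count ran from 7 to 136 over 9 choices, with a median of 31. Of these, 5 choices gave 39 or fewer, so the smaller number of arrays may account for the lower count. Each choice was normalized and fitted with fewer arrays in all than the fit that gave 39. Its estimate of the spread was less precise, which may itself lower these counts. Whether responses were smaller in the rescue-labelled line cannot be told from 55 chaperone and heat-inducible genes as a set. These genes had a small median response in both lines, and their median difference was close to 0 relative to its spread. Their median response was 0.226 log2 in KO-labelled and 0.252 in rescue-labelled arrays. The median difference was 0.0036 log2 (median absolute deviation 0.188), 28 genes lay above 0 and camera gave p = 0.509 with an estimated correlation. Among them the 5 small heat shock proteins had a median difference of -0.120, with 0 values above 0. Smaller responses stay open for other genes as well: immediate early genes had a median difference of -0.380, with 2 of 25 values above 0. The 10 splits of the 6 KO-labelled arrays are too few for a share under 0.05; the real split called 193 genes, a count reached by 1 split, itself, and the highest other called 1, and of the 4 splits that part all 3 pairs the other 3 called 0 (limma, 77 to 158 unadjusted).

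Immediate early genes had a median difference of responses of -0.380 log2 (rescue minus KO), listed because camera at the preset correlation called the difference itself (adjusted p = 4.97e-08, but 0.769 with an estimated correlation and 0.919 by fry). Leaving out each of 10 arrays ended the call at the preset correlation or turned the sign in 0 cases. The medians ran from -0.499 to -0.192 (-0.192 without rescue preshocked replicate 1 and -0.197 without KO preshocked replicate 1). That argues against 1 array deciding the direction, while the size depended on single arrays. Whether 1 array decides the call cannot be told, since the call does not hold with an estimated correlation. Genes of the list that vary together from array to array may account for it, since camera with an estimated correlation gave an unadjusted p = 0.0590, and the list mean was 11.30 in KO preshocked replicate 1 against 10.65 and 10.54 in the other KO-labelled preshocked arrays (without the pair labelled 5 and 6 the median was -0.193). Between the lines the list median was 0.309 in unheated and -0.074 in preshocked cells, and the unheated list means were 10.41 and 10.31 in rescue-labelled against 9.91, 9.98 and 10.01 in KO-labelled arrays. A biological difference between the lines stays open and was not tested apart from these.

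ATF4 and the integrated stress response had a median difference of responses of -0.146 log2 and was called by the same test (adjusted p = 0.0105, but 0.769 with an estimated correlation and 0.919 by fry), a call that ended without KO preshocked replicate 1 (0.266), rescue preshocked replicate 1 (0.284), rescue unheated replicate 1 (0.457), KO unheated replicate 1 (0.0545), KO unheated replicate 2 (0.117) or KO unheated replicate 3 (0.0859). Histone genes had a median difference of 0.152 log2 and passed by fry (adjusted p = 0.0400), against camera adjusted p = 0.265 and 0.769 with an estimated correlation. A probe set with no gene symbol, outside the genes compared, rose after preshock in KO-labelled arrays by 2.40 ± 0.24 log2 (adjusted p = 0.0230 among probe sets with no single symbol).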

How the results depend on the processing

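The alternatives without the pair labelled 5 and 6 were chosen only after the result was seen. No called result was called in the other direction under any alternative, though the median of Hox genes in rescue-labelled arrays went from 0.203 to -0.060 without rescue unheated replicate 2. The correlation of responses stayed positive, and the calls of Atf3, Cpn1, Fosb, Hspa1b, Mmp13, Pgf and Ttc30b in KO-labelled arrays and of Cpn1 in rescue-labelled arrays held under every alternative run for them in the fit of genes, while the Hspa1b probe sets fitted among all probe sets did not keep theirs. Named genes lost a call in 225 gene and alternative combinations in KO-labelled arrays, 176 in rescue-labelled arrays, 149 for the unheated and 76 for the preshocked lines, and gained one in 77, 35, 14 and 30. Lists lost a call in 17, 20, 16 and 4 combinations (KO, rescue, difference of responses, unheated lines) and gained one in 8, 15, 4 and 0, and in 1 for the preshocked lines. Causes were not tested except where fewer arrays or other sets of genes change the test itself. A fit on only the compared groups was not run for the difference of responses, which uses every group. Signal over background limits what dim genes show: with no filter on them the correlation of responses was 0.175.

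For preshock in KO-labelled arrays (193 genes), the count was 27 centred on medians (24 higher), 28 with no filter on dim genes (24 higher), 44 with only the compared groups, 101 with the mean of probe sets, 1000 with the pair block and 1610 with array weights, and 49 to 142 with 1 array left out. Without the pair labelled 5 and 6 it was 136. For preshock in rescue-labelled arrays (39 genes), it was 7 centred, 10 with no filter, 60 with an intensity trend, 1 with only the compared groups (Cpn1), 166 with the block and 104 with array weights, and 10 to 12 with 1 array left out. The difference of responses had 1 gene with no filter (3632454L22Rik, 6.66 log2, adjusted p = 0.0437) and 0 by limma in the other alternatives, with 25 to 545 at an unadjusted p under 0.05. For the unheated lines (46 genes), it was 10 with no filter, 0 with only the compared groups (limma, 1170 unadjusted), 20 with the mean of probe sets, 22 with the block, 198 with array weights, 95 without the pair labelled 5 and 6, and 5 to 22 with 1 array left out. For the preshocked lines (37 genes), it was 22 centred (15 higher), 6 with no filter, 23 with the 40% of genes with the highest mean, 3 with only the compared groups (B3galnt1, Fez1 and Mapk12), 9 with the mean of probe sets, 16 with the block, 703 with array weights, 64 without the pair labelled 5 and 6, and 0 to 15 with 1 array left out. The cause was not tested. Where leaving out 1 array leaves a group with 1, that array is assumed to vary like the other groups. The array weights were 5.09 for KO preshocked replicate 2 and 3.32 for KO unheated replicate 2. The other KO-labelled arrays had weights of 0.325 to 0.763. Counts with array weights that use KO-labelled arrays therefore rest largely on the arrays named replicate 2.

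The correlation of responses, 0.650, was 0.175 with no filter, 0.848 with the 40% of genes, 0.712 with the offset and 0.537 with the mean of probe sets, and 0.565 to 0.615 with 1 array left out. Lists called fell from 9 to 0 with an estimated correlation in each line after preshock. In KO-labelled arrays G2 and M phase was called as higher with the deposited values (camera adjusted p = 0.00353) and an intensity trend (0.0473). It was also called with the mean of probe sets (0.0466) and array weights (0.0479). Proteasome subunits were called as higher with the deposited values in KO-labelled (0.00495) and rescue-labelled arrays (0.00237). In rescue-labelled arrays centring (0.0366) and the mean of probe sets (0.0488) also called them. In KO-labelled arrays other list calls ended for Hsp90 machinery and metal response with the mean of probe sets (0.165 each), for cholesterol synthesis with centred arrays (0.188) and without the pair labelled 5 and 6 (0.0693, and 0.0619 with the block), and for ATF4 and the integrated stress response by fry (0.0686). In rescue-labelled arrays they ended for Hsp90 machinery with centred arrays (0.0715), for the Hsp70 and Hsp110 family (0.0562), Hsp90 machinery (0.0555) and Hox genes (0.130) with no filter, and by fry for immediate early genes (0.401), G2 and M phase (0.0503) and Hox genes (0.490). For the difference of responses 2 lists became 1 with the deposited values, centred arrays, no filter, the mean of probe sets, array weights or without the pair labelled 5 and 6, 0 with an estimated correlation, and 1 to 3 with 1 array left out. By fry both calls ended (0.919 each) and 1 other list, histone genes, was called (0.0400). For the unheated lines 1 list became 0 with an estimated correlation or fry, and 0 to 1 with 1 array left out, and for the preshocked lines 0 became 1 with the deposited values (cholesterol synthesis, adjusted p = 0.0496, against 0.968 with an estimated correlation).

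For the 3 Hspa1b probe sets, taken in the order of their rise and fitted among all probe sets, the sizes stayed while calls ended. In KO-labelled arrays all ended with the block (8.48, 7.78 and 6.81), as did the last with only the compared groups (6.81) and without the pair labelled 5 and 6 (6.60). Without that pair and with the block all ended (8.37, 7.74 and 6.60). In rescue-labelled arrays the last 2 ended with centred arrays (6.74 and 5.78). All ended with only the compared groups and with the block (6.95, 6.55 and 5.60), and with each array left out (6.78 to 7.09, 6.44 to 6.64 and 5.29 to 5.90). Between the unheated lines the probe set with the largest rise (1.82) was called with an intensity trend. The cause was not tested.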

Other observations

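The tests of genes named Zfp and of imprinted genes were chosen only after the result was seen.

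Genes called in both lines after preshock and not described so far included Mmp13, a collagenase gene, higher by 1.80 ± 0.20 log2 in KO-labelled and 1.74 ± 0.25 in rescue-labelled arrays, Socs3, a suppressor of cytokine signalling (1.39 ± 0.16 and 1.65 ± 0.20), and the phosphatase gene Dusp4 (1.54 ± 0.16 and 1.96 ± 0.19). The transcription factor gene Maff was higher by 1.54 ± 0.20 and 1.56 ± 0.24. In KO-labelled arrays the 4 stayed called without each array. With centred arrays Socs3, Dusp4 and Maff lost their calls there (adjusted p = 0.132, 0.155 and 0.112). Socs3 and Maff also lost them with no filter on dim genes (0.0547 and 0.0561), and Maff with only the compared groups (0.0700). With centred arrays the 4 genes lost their calls in rescue-labelled arrays too (0.155 to 0.353). In rescue-labelled arrays Mmp13, Dusp4 and Maff lost their calls without each of the 4 arrays, rescue preshocked replicates 1 and 2 and rescue unheated replicates 1 and 2 (adjusted p from 0.143 to 0.227, 0.0553 to 0.0732 and 0.206 to 0.275). Socs3 lost it without rescue preshocked replicate 1 (0.14997) or 2 (0.0553) and rescue unheated replicate 1 (0.107), and Maff also with the pair block (0.0632, range over all alternatives 0.00923 to 0.353). These 4 genes were named after their values were seen, and the difference of responses was not called for any gene.

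Because 4 genes named Zfp were among the largest falls in KO-labelled arrays, a hypothesis is that genes with this name, which encode zinc finger proteins, fall more than other genes of like signal. Over the other 246 such genes tested, the median change was -0.257 log2 in KO-labelled and -0.274 in rescue-labelled arrays, and 0 of 10000 random lists matched for mean signal had a median as low in either line. The medians of the random lists were -0.069 and -0.052 at their middle and -0.154 and -0.171 at their lowest. Among the Zfp genes 72.4% and 71.1% had negative values, against 58.0% and 55.1% of other genes. Over all 250 Zfp genes, 9 were called lower in KO-labelled and 1 in rescue-labelled arrays, and 0 higher in either by limma. The random lists take no account of genes that vary together: camera with an estimated correlation gave p = 0.145 and 0.199, so the fall of the group may rest on shared variation between arrays.

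Ndn, Phlda2 and Peg3, which differed between the lines, are imprinted, and a hypothesis is that imprinted genes differ between the lines more often than other genes. Without these 3, 1 of 9 measured imprinted genes had an unadjusted p under 0.05 in unheated cells, 11.1% (exact Clopper-Pearson upper limit 48.2%), against 12.9% of other genes (two-sided Fisher exact p = 1). In preshocked cells it was 2 of 9 (two-sided Fisher exact p = 0.366). The 9 genes are too few to decide it. With the 3 genes that prompted the list, it was 4 of 12 in unheated cells (two-sided Fisher exact p = 0.0584) and 5 of 12 in preshocked cells (0.0182). Those shares include the genes for which the list was made, so they cannot test the hypothesis. Meg3 stood at -1.98 ± 0.55 between the unheated lines without being called.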
